A study of Mus musculus with 16 samples.

How the data were processed

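The samples were 16 bulk ATAC-seq libraries of cells sorted by flow cytometry from femurs of 3-month-old mice homozygous for the D257A change in PolG, the polymerase that copies mitochondrial DNA. The D257A change removes its proofreading activity, so that mitochondrial DNA gathers mutations at a high rate. Per the labels' protocols, bones were digested mechanically and with enzymes, sorted cells were lysed, their DNA was cut and tagged with Tn5 transposase, and the libraries were sequenced on a NovaSeq6000 as paired-end reads of 100 bp. Open DNA is read preferentially by this assay, and mitochondrial DNA, which carries no nucleosomes, is read at great depth. The 8 sorted subsets are named by the markers in their labels (CD45, Thy, 6C3, Thy_6C3, CD105, CD24, CD24_CD29 and CD29), each with replicates 1 and 2. The labels do not give the gates, and they do not say which mice or how many gave each library, so p-values measure only the spread between these libraries, which may be technical.

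The deposited tables hold whole-number counts, not normalized by the authors: the coverage of each position of the mitochondrial genome in each library, and the count of each non-reference base at that position. Per the submitters' processing notes, bcl2fastq 2.20, cutadapt 2.10 and BWA 0.7.17 were used with the builds GRCm38 and mm10, without a role for each. Filters on base or mapping quality, removal of duplicate reads and the handling of nuclear copies of mitochondrial DNA are not given in the sources used here. Each of these steps can change a low allele fraction. Duplicate reads count as independent reads in the intervals below, and reads from nuclear copies would appear as non-reference bases at fixed positions. The usual shift of read ends toward the Tn5 cutting site does not enter a count of bases per position.

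An allele was a position with 1 of its 3 non-reference bases, over 16299 positions and 48897 alleles. An allele is written as the reference base, the position counted from 1 in the GRCm38 mitochondrial sequence, and the non-reference base. The allele fraction was the allele's count divided by the coverage. Genes and codons came from the RefSeq annotation of assembly GRCm38.p6, and protein changes from the vertebrate mitochondrial code on the reference bases in the deposited tables. Mutation load was the mean over positions of the summed non-reference fraction. An allele was counted in a library at a fraction of 1% or more with at least 5 counts, and no position differed from the reference at 50% or more, so no strain difference was left out. The transition share was the percent of counted alleles that were A>G, G>A, C>T or T>C. A widespread allele was counted in all 8 libraries of a replicate number and a restricted allele in exactly 1.

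Mean coverage per library ran from 6569 to 77252 counts per position, and the lowest coverage at any position in any library was 2391. A count of 0 therefore allows, at 3 counts of the mean coverage, a fraction of up to 0.0457% in the shallowest library and 0.00388% in the deepest. Fractions of single libraries are given with exact (Clopper-Pearson) 95% intervals. Intervals and limits cover counting error only, since reads carry no molecular identifiers.

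Depth, load, allele number and transition share were compared between subsets by the share of the variance that lies between subsets, with an exact permutation test over all 2027025 ways to pair 16 libraries, one-sided for a larger share and adjusted over the 4 measures by the Benjamini-Hochberg method. Sharing within a replicate number was the mean correlation of allele fractions (arcsine square root scale) between different subsets of the same number minus that between different numbers, with an exact test over 128 swaps of numbers within subsets. Differences between subsets per allele were tested with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3, 8 residual degrees of freedom, threshold 0.05). The fit took the non-reference and reference counts of each library as a pair of columns. It held a term per library and, for the non-reference column, a term per subset. Tests ran over all subsets at once and for each subset against the mean of the other 7. Libraries of a replicate number were compared per allele with a chi-square test. Distances between subsets were root mean square differences of arcsine square root fractions within a replicate number, compared between numbers over all 40320 relabellings of the subsets. Widespread and restricted alleles were compared with Fisher's exact test, two-sided. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and Biopython 1.88 were used for the rest.

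The subsets, tests, thresholds, gene groups, the rule for named alleles and most alternatives were chosen before the data were examined. The rule named, for each contrast, the 3 alleles with the largest difference among those that passed or else the allele with the smallest p, the 5 alleles with the highest mean and the 5 with the largest range in each replicate number, and in each library the highest allele counted in that library alone within its number. Other alleles named in the text were chosen after their values were seen. Alternatives were a coverage minimum, other fraction thresholds, thinning to equal coverage, counts divided by 10, a replicate block, a quasi-binomial model, DESeq2 1.42.0, no fraction filter and leaving out each library or each subset. Subset tests with a single library left out, settings without Thy replicate 2, a 2% threshold and restrictions to alleles of several libraries or of a single replicate number were added after the data were seen.

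Replicate numbers come from the labels. The deviations of libraries from their subset means were correlated over subsets of the same number in 28 of 28 pairs of subsets above 0.1 (0.267 to 0.863, median 0.658), so the numbers were taken to pair the libraries. Blocked values are given where they change a call.

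The allele test was tested on simulated data drawn for 3487 alleles with the CD24_CD29 contrast. With a spread between libraries of 0.3 (SD, logit scale), edgeR recovered 52% of 50 alleles changed 2-fold, 98% at 4-fold and 100% at 8-fold and 16-fold, with 10 false calls. The real alleles varied more, with a median SD of 0.544 between the libraries of a subset, and 94.1% of them had an SD above 0.3. With each allele's measured spread, which includes counting error, edgeR recovered 0% at 2-fold, 34% at 4-fold, 62% at 8-fold and 86% at 16-fold, with 1 false call. DESeq2 then recovered 64% at 4-fold with 25 false calls, and the quasi-binomial model 44% with 13. In both simulations the spread was drawn independently for each library, although the real deviations correlated within a replicate number. Recovery was scored for the CD24_CD29 contrast alone, not for the test over all subsets. The chi-square test, on 493 simulated alleles of replicate 1, recovered 84% of 100 alleles changed 1.5-fold and 99% of 100 changed 2-fold, with 4 false calls among 293 unchanged. Chromatin accessibility of the nucleus was not analysed here.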

Results

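Mitochondrial DNA was read in 8 sorted cell subsets from femurs of mice with a proofreading-deficient mitochondrial DNA polymerase, with 2 libraries per subset. The comparisons address how high the non-reference fraction is in each subset, which alleles are shared between subsets, and whether subsets stand in the same relation in both replicates. CD45 is a marker of blood-lineage cells. The other labels name Thy, 6C3, CD105, CD24 and CD29, surface markers used to part skeletal cell populations.

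Mitochondrial coverage was highest in CD29 cells, at a mean of 57037 counts per position ± 28588 (SD, n = 2), and lowest in CD24_CD29 cells, at 10052 ± 4925 (SD, n = 2). Between these stood CD105 (31811), 6C3 (30177), Thy (24259), CD45 (19721), Thy_6C3 (17647) and CD24 (16907). The total coverage of a library ran from 107069406 counts in CD24_CD29 replicate 2 to 1259128217 in CD29 replicate 1. Coverage was not scaled to all reads of a library or to cell number, so it does not measure mitochondrial DNA content. Subsets held 79.1% of the variance of log-scale depth (exact permutation p = 0.0108, one-sided, 0.0430 after adjustment over 4 measures). Without both CD24_CD29 libraries the exact permutation p was 0.0572, and without both CD29 libraries it was 0.0505. Of the 16 single libraries, leaving out CD24_CD29 replicate 2 (exact permutation p = 0.0611) or CD29 replicate 1 (exact permutation p = 0.0561) ended the call.

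**Figure D1:**
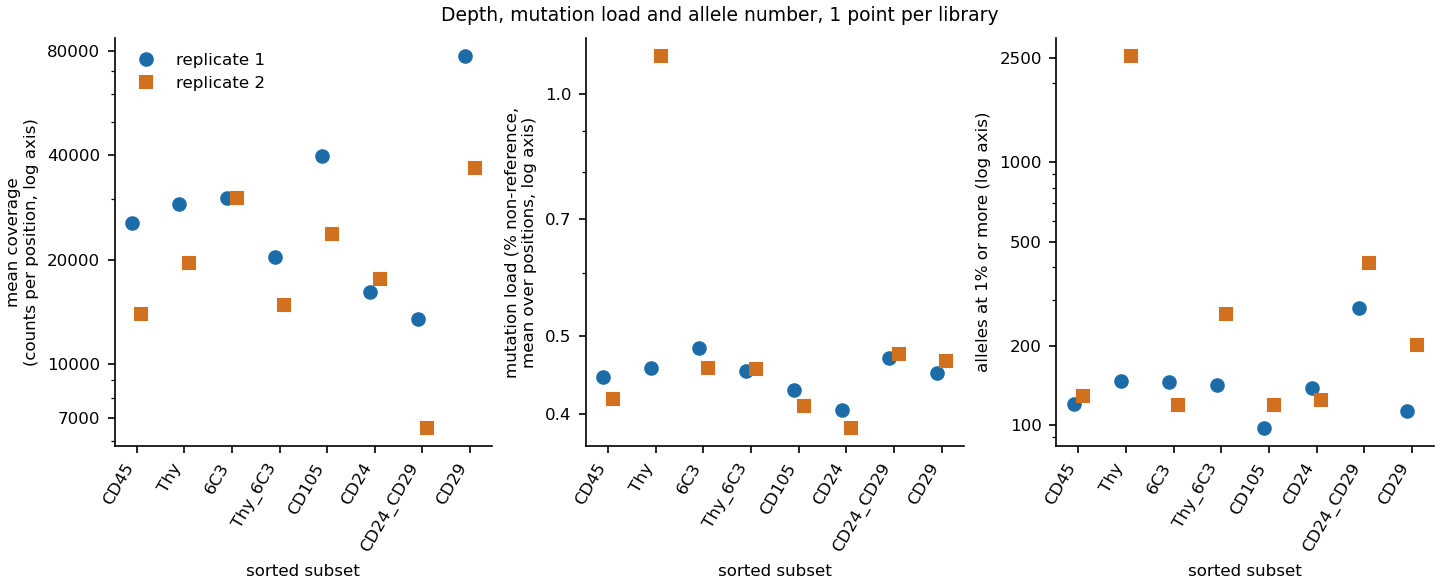
Mean coverage, mutation load and number of alleles at 1% or more per library, each on a log axis, with subsets on the horizontal axis, circles for replicate 1 and squares for replicate 2. Thy replicate 2 stands apart in load (1.11%) and in allele number (2530), and CD24_CD29 has the lowest coverage in both replicates.

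Mutation load, which counts all non-reference bases and so includes sequencing errors, ran from 0.385% to 0.484% of bases per position in 15 libraries. C>A and G>T changes had mean fractions of 25.4 to 35.0 per 10000 in these, against 11.3 to 13.9 for C>T, and G>T over C>A was 0.999 to 1.03 in all 16 libraries. Without the Thy subset these 2 changes also differed between subsets (adjusted exact permutation p = 0.00988 for both, one-sided). It was lowest in CD24 cells at 0.395% ± 0.0139 (SD, n = 2) and CD105 cells at 0.419% ± 0.0138, and reached 0.470% ± 0.0190 in 6C3 and 0.473% ± 0.00423 in CD24_CD29. CD45 cells had 0.431% ± 0.0193, Thy_6C3 cells 0.454% ± 0.00128 and CD29 cells 0.458% ± 0.0107. Thy replicate 1 had 0.456%, within the range of the other subsets, while Thy replicate 2 had 1.11%. With that library included, subsets did not differ beyond the spread between libraries (exact permutation p = 0.250, one-sided). Without the Thy subset, 88.9% of the variance lay between the other 7 subsets (exact permutation p = 0.00598). The exact permutation p was 0.00866 without Thy replicate 2 alone and 0.000399 without Thy replicate 1 alone, where the library left in a subset adds nothing to the spread within subsets. Most of the load came from alleles under 1%. Alleles at 1% or more gave a load of 0.0163% and 0.0189% in CD105, 0.0200% and 0.0187% in CD24 and 0.0327% and 0.0461% in CD24_CD29. In this part of the load CD105 was below CD24 in replicate 1 alone, while in the whole load CD24 was lower in both replicates. Between subsets, the exact permutation p was 0.270 for the load of alleles at 1% or more and 0.0993 for that of alleles under 1%.

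Alleles at 1% or more numbered 98 to 416 in 15 libraries and 2530 in Thy replicate 2. The most among the 15 were in the CD24_CD29 libraries, with 280 and 416, and CD105 had the lowest mean, with 98 and 120. Of the CD24_CD29 alleles, 163 and 275 were counted in no other library of the same replicate number. In Thy replicate 2, 2178 alleles were A>C or T>G changes, against 13 to 36 in each of the other 15 libraries. The number of alleles did not differ between subsets beyond the spread between libraries (exact permutation p = 0.270, one-sided), but did without the Thy subset (exact permutation p = 0.0325). It did not pass without Thy replicate 2 alone. Without Thy replicate 1 alone, Thy replicate 2 stands by itself in its subset and adds nothing to the spread within subsets. That setting therefore cannot show a difference between subsets, for allele number or for the transition share. Transitions made up 53.5% to 70% of alleles in the 15 libraries and 3.79% in Thy replicate 2 (exact permutation p = 0.135, one-sided). With a threshold of 0.5% the latter p was 0.00140 by the exact permutation test, and with alleles weighted by their fraction it was 0.0296.

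Libraries with the same replicate number were more alike in their allele fractions than libraries of different numbers. Allele fractions of different subsets correlated at a mean of 0.735 (0.137 to 0.954) within a number and 0.317 (-0.0767 to 0.462) across numbers, over alleles, which are not independent replicates. Each of the 16 libraries was closest to a library of another subset with the same number. The difference of 0.418 was the largest of 128 swaps of the numbers (exact permutation p = 0.00781, one-sided, the smallest the design can give), and the highest value of any other swap was 0.231.

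**Figure D2:**
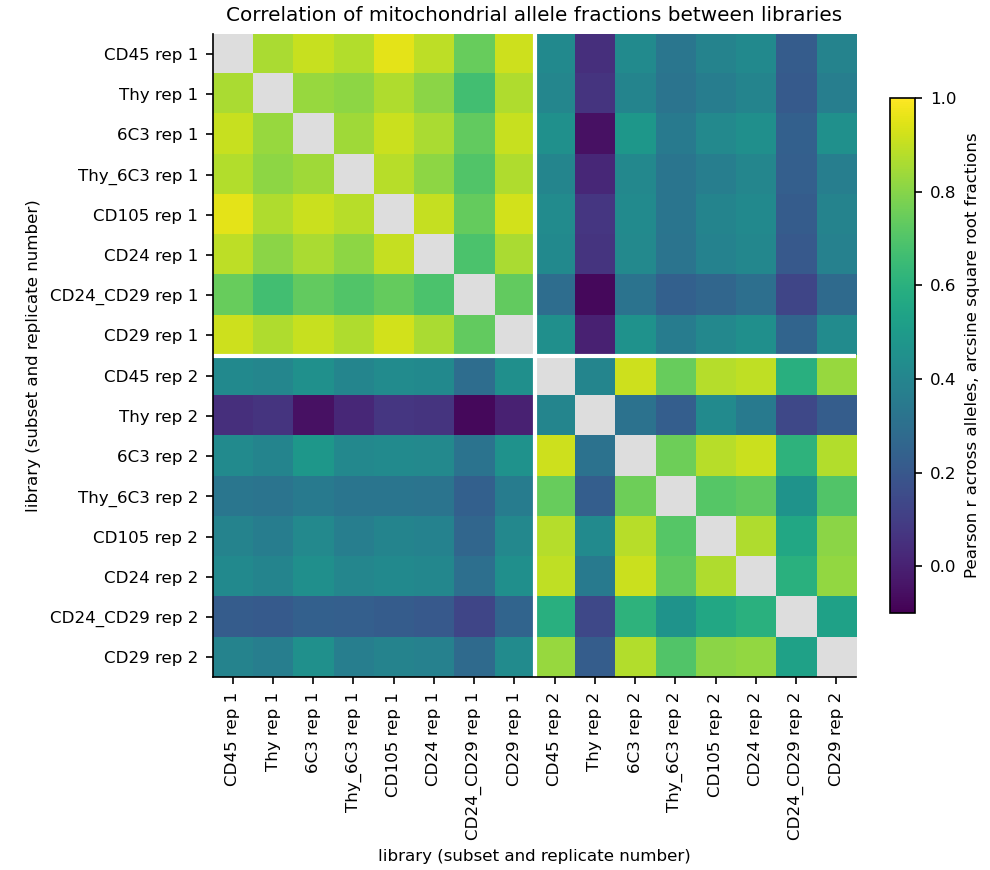
Correlation of allele fractions (arcsine square root scale) between each pair of the 16 libraries, with libraries of replicate 1 first and those of replicate 2 after them on both axes. Correlations between subsets average 0.735 within a replicate number and 0.317 across numbers.

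In replicate 1, 493 alleles reached 1% in at least 1 library, and 53 did so in all 8 libraries, while 320 did so in a single library. In replicate 2 these numbers were 3126, 59 and 2909. The highest allele of replicate 1 was C10658T, a synonymous change (L164L) in ND4, a subunit of respiratory complex I, at 18.5% ± 2.06 (SD, n = 8 libraries). G3079A (S110N in the complex I gene ND1) followed at 17.8% ± 2.06. C7953T, which lies in the overlap of the ATP synthase genes ATP8 (S63L) and ATP6 (F9F), stood at 10.7% ± 2.2. T2674A in the large ribosomal RNA gene mt-Rnr2 had 9.44% ± 1.48, and C7166T (H52Y in COX2, a subunit of cytochrome c oxidase) 9.34% ± 1.35.

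The highest allele of replicate 2 was C11959T (S73L in the complex I gene ND5) at 22.4% ± 1.97 (SD, n = 8 libraries). It was followed by C1051T in TrnV, the valine transfer RNA gene, at 14.8% ± 2.42. C14024T (C16Y in the complex I gene ND6) had 9.10% ± 1.01, C3085T (S112L in ND1) 7.74% ± 1.41 and T13093A (M451K in ND5) 7.57% ± 1.45. In the other replicate number, C11959T averaged 0.269% ± 0.213 and C1051T 0.0820% ± 0.0334. C10658T averaged 0.650% ± 0.244 and G3079A 0.331% ± 0.190 in replicate 2. C7166T and C14024T were high in both, with 6.49% for C7166T in replicate 2 and 5.26% for C14024T in replicate 1. C11959T lies at position 11959 of the mitochondrial chromosome, in the reference sequence ACCATAAATTCAATAGAACTT from 11949 to 11969, within ND5 (11742 to 13565). C10658T lies in TAATTGCCCTCATCTTAATCC from 10648 to 10668, within ND4 (10167 to 11544).

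Alleles at 1% or more in all 8 libraries of a number and under 0.5% in every library of the other, a class described after the values were seen, numbered 12 in replicate 1 and 15 in replicate 2. C>T changes made up 9 of each. Complex I genes, which cover 6340 of the 16299 positions, held 10 of the 12 and 8 of the 15. The control region, which holds the replication origin of the heavy strand, held 0, but it covers only 5.38% of positions. Enrichment of this class in complex I genes was not tested. In replicate 1 they ran from C4866T (T318M in ND2) at 2.14% ± 0.379 to C4093T (F60F in ND2) at 6.99% ± 1.22, and included G9775A, a stop (W106*) in ND3, at 2.21% ± 0.446 (SD, n = 8). In replicate 2 they ran from C11260T (A365V in ND4) at 1.56% ± 0.503 to C1051T.

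**Figure D3:**
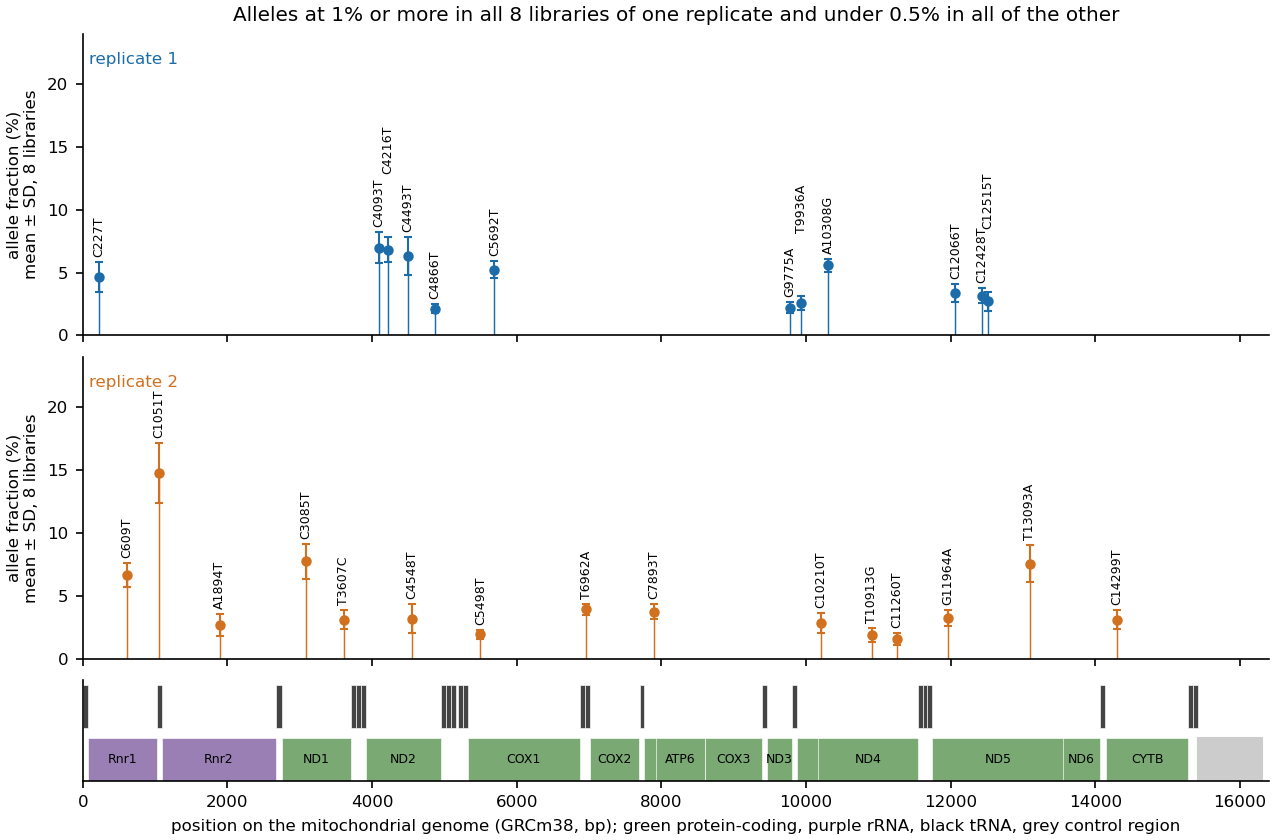
Position on the mitochondrial genome (bp) of the 12 alleles of replicate 1 and the 15 of replicate 2 that were at 1% or more in all 8 libraries of that number and under 0.5% in the other, with the mean allele fraction (%) and SD over 8 libraries, above the genes. The highest is C1051T at 14.8%, and the control region holds none.

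C14338T (S65L in CYTB, the cytochrome b of complex III) was at 9.09% (95% exact interval 8.73 to 9.46) in CD24_CD29 replicate 1 and at no more than 0.445% in the other 7 libraries of replicate 1. T14914C (M257T in CYTB) was at 7.04% (6.70 to 7.39) in the same library and at no more than 0.459% in the others. T2542G in mt-Rnr2 was at 6.94% (6.57 to 7.32) in CD105 replicate 2, where the neighbouring T2539G and T2540G had 7.64% and 6.07%. In CD24_CD29 replicate 2, C635T in mt-Rnr1 was at 4.29% (3.70 to 4.95), but it averaged 2.76% over replicate 1. In Thy replicate 1, A5278C in TrnY was at 4.04% (3.80 to 4.29), and in Thy replicate 2 A5202C in TrnC was at 3.46% (3.2 to 3.74).

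Of the other alleles counted in a single library of a replicate number, the highest in CD24 replicate 1 was A10457C (S97S in ND4) at 2.32% (2.12 to 2.54) and in Thy_6C3 replicate 2 C7913T (P50S in ATP8) at 2.09% (1.87 to 2.33). CD29 had T14833C (L230P in CYTB) at 1.92% (1.84 to 2.0) in replicate 1 and T3200C (L150L in ND1) at 2.07% (1.91 to 2.25) in replicate 2. Thy_6C3 replicate 1 had C14248A (S35Y in CYTB) at 1.61% (1.44 to 1.80), 6C3 replicate 2 had A14188T (N15I in CYTB) at 1.46% (1.34 to 1.59) and CD45 replicate 2 had T15014C (G290G in CYTB) at 1.44% (1.27 to 1.63). In 6C3 replicate 1 and CD24 replicate 2 the highest were T13404C (L555L in ND5) at 1.26% and C3925T (I4I in ND2) at 1.25%. The 2 lowest of these alleles lay just above 1%. T9246G (F214V in COX3) was at 1.14% in CD45 replicate 1, at 0.843% to 0.967% in the others of that number and at 2.85% in Thy replicate 2. A16065C in the control region was at 1.09% in CD105 replicate 1, at no more than 0.987% in the others of that number and at 2.33% in Thy replicate 2.

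Within a replicate number, allele fractions differed between libraries by more than counting error at 475 of 493 alleles in replicate 1 and 3121 of 3126 in replicate 2 (chi-square test, adjusted over alleles). This test compares libraries, not subsets. Alleles were tested if any of the same libraries reached 1%, and 320 and 2909 of them did so in exactly 1 library. The filter thus favoured alleles that differ, so these shares do not describe mitochondrial alleles at large. With all counts divided by 10, 389 and 2918 still differed. Without Thy replicate 2, 738 alleles of replicate 2 differed, with alleles chosen anew.

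Without a replicate block, no allele passed the edgeR test for a difference between subsets. With the replicate number as a block, edgeR called 0 alleles over all subsets, 2 for Thy and 1 for Thy_6C3. The CD24_CD29 contrast was simulated with each allele's measured spread, drawn independently for each library. There edgeR recovered 0% of 2-fold and 34% of 4-fold changes, so differences of this size are not ruled out. The test over all subsets was not simulated, so its power is not known. Of 3487 alleles at 1% or more in at least 1 library, edgeR's quasi-likelihood test called 0 over all subsets (lowest adjusted p = 0.885, 53 at an unadjusted p under 0.05), and DESeq2 called 18. In the contrasts of each subset with the mean of the other 7, edgeR without the block called 0 alleles in all 8. Unadjusted p under 0.05 was reached by 1702 alleles for Thy, 220 for CD24_CD29, 110 for Thy_6C3, 43 for CD24, 31 for CD29, 17 for 6C3, 6 for CD105 and 4 for CD45, where chance gives 174. Thy replicate 2 held 2530 counted alleles, and 2373 of them were counted in no other library of its replicate number. Many tested alleles thus passed the filter by being high in a Thy library, so the Thy counts of any model cannot be set against chance. The same holds for CD24_CD29, whose libraries held 163 and 275 alleles counted in no other library of their replicate number. Since the filter took alleles high in a single library of any subset, 174 is no fair mark for any of the 8 counts. Without Thy replicate 2 the counts at an unadjusted p under 0.05 were 95 for Thy and 58 to 465 over the 8 contrasts, and without Thy replicate 1 they were 198 to 2425. DESeq2 called 2024 for Thy, 67 for CD24_CD29 and 6 for Thy_6C3, and a quasi-binomial model 2259 for Thy and 30 for CD24_CD29. Without Thy replicate 1, edgeR called 2298 alleles over all subsets, 2396 for Thy, 147 for CD24 and 1 for 6C3, without Thy replicate 2 it called 2 for Thy, and without CD24_CD29 replicate 1 it called 25 for CD24_CD29.

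The alleles nearest to a call lay in transfer RNA genes for Thy. A5277C in TrnY was at 2.60% and 0.327% in the Thy libraries, against means of 0.0127% and 0.0253% in the other subsets (adjusted p = 0.0984 with edgeR). It passed with DESeq2 (adjusted p = 9.94e-11), with the quasi-binomial model (0.0323) and with edgeR without Thy replicate 1 (0.000907), without Thy replicate 2 (0.0477) and without CD24_CD29 replicate 2 (0.0493), but not without Thy replicate 2 when alleles were chosen anew (0.243), with no fraction filter (0.0868) or at a threshold of 2% (0.102). With the replicate number as a block the adjusted p was 0.0265, and T5201G in TrnC, at 0.910% and 1.45% in Thy and no more than 0.188% elsewhere, passed at an adjusted p of 0.0191 with edgeR. The mean over positions in Thy replicate 2 was 76.5 per 10000 for A>C and 66.5 for T>G, so its 0.327% at A5277C lay below the mean for that change. A13962G (F37L in ND6) was at 0.0264% and 0.0368% in Thy_6C3, against 0.156% or more in every other library. Its adjusted p with edgeR was 0.104, and 0.0488 with the block, and with DESeq2 it was 0.000406, while with the quasi-binomial model it was 0.835 and with no fraction filter 0.3.

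For the other subsets the allele with the smallest p did not pass in edgeR. C8752T (T49I in COX3) was at 0.473% and 1.12% in CD24_CD29, against means of 0.0761% and 0.0904% in the others (edgeR adjusted p = 0.210), and it passed with DESeq2 (adjusted p = 3.85e-06) but not with the quasi-binomial model (0.161) or the replicate block (0.0814). It had 0 counts in both CD24 libraries, which allows up to 0.0188% and 0.0184% (edgeR adjusted p = 0.978, and 0.0486 without Thy replicate 1). C12947T (C402C in ND5) was at 0.423% and 1.15% in CD29, A13866G (Y69H in ND6) at 1.03% and 0.519% in 6C3, C7533T (A174V in COX2) at 1.1% and 0.279% in CD45, and T325C in mt-Rnr1 at 0.146% and 0.0165% in CD105. Their adjusted p with edgeR ran from 0.985 to 1.0.

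The subset farthest from the rest was CD24_CD29 in replicate 1, at a mean distance of 0.0509, and Thy in replicate 2, at 0.0640. Pairs with CD24_CD29 were farther apart than all other pairs in replicate 1, and pairs with Thy were in replicate 2. Among the other 6 subsets r was 0.568 (exact permutation p = 0.136, one-sided) and rho was 0.486 (exact permutation p = 0.147). Over all 28 pairs, the test chosen in advance gave r = 0.386 (exact permutation p = 0.127) and rho = 0.681 (exact permutation p = 0.0348). Without Thy alone, r was 0.902 (exact permutation p = 0.0216), and without CD24_CD29 alone it was 0.660 (exact permutation p = 0.0143).

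**Figure D4:**
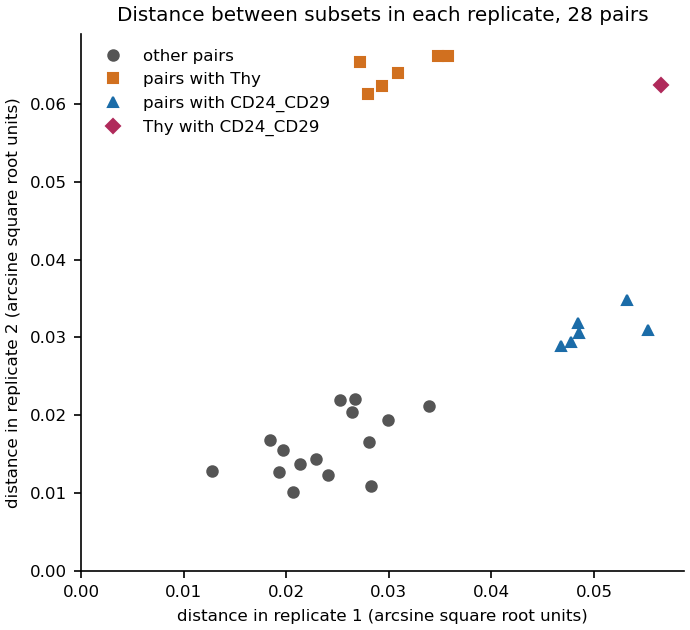
Distance between each pair of subsets (root mean square difference of arcsine square root allele fractions) in replicate 1 on the horizontal axis and replicate 2 on the vertical axis, 28 pairs. Pairs that include Thy lie high in replicate 2 and pairs that include CD24_CD29 lie far out in replicate 1.

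The blood-lineage CD45 cells were not the most distant subset. Their mean distance to the 7 skeletal subsets differed from the mean among those 7 by -0.00953 (exact permutation p = 0.953, one-sided), and CD45 ranked 7 of 8 in both replicates. Alleles counted in a single library enter these distances. CD45 libraries held 5 and 11 of them and CD24_CD29 libraries 163 and 275. The rank of CD45 therefore cannot be read as a statement about lineage. Subsets that share a marker were not closer to each other either. The 4 such pairs were farther apart than the other 17 by 0.00680 (exact permutation p = 0.900, one-sided). Among these 4 are CD24 and CD29 with CD24_CD29, and Thy with Thy_6C3. CD24_CD29 in replicate 1 and Thy in replicate 2 were far from every other subset. The test therefore cannot part marker sharing from these outlying libraries.

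Widespread alleles lay more often in the control region than restricted ones. In replicate 1, 18 of 53 widespread alleles (34.0%) and 7 of 320 restricted alleles (2.19%) did so (odds ratio 23.0, Fisher's exact p = 7.73e-12, two-sided), and in replicate 2, 18 of 59 (30.5%) and 146 of 2909 (5.02%) did (odds ratio 8.31, p = 8.28e-10, Fisher's exact test). The test chosen in advance pooled both replicates and gave an odds ratio of 9.52 (Fisher's exact p = 3.47e-19, 1.74e-18 after adjustment over 5 tests). It counts the 24 alleles that were widespread in both replicates under each of them, takes 2373 restricted alleles from Thy replicate 2, and treats neighbouring alleles as independent. Without Thy replicate 2 the odds ratio was 23.1 (Fisher's exact p = 3.41e-24). Protein-coding genes held a smaller share of widespread than of restricted alleles, with an odds ratio of 0.412 in replicate 1 (Fisher's exact p = 0.00459), 0.355 in replicate 2 (p = 0.000157), 0.350 over both (p = 8.71e-08) and 0.432 without Thy replicate 2 (p = 4.79e-05). In replicate 1, 25 of 53 widespread alleles lay in protein-coding genes and 18 in the control region, against 219 and 7 of 320 restricted alleles. Shares of the same list are linked, so the control region excess lowers the protein-coding share. The lower share cannot be read as a separate result. Complex I genes held 18 widespread alleles in replicate 1 and 19 in replicate 2, complex IV genes 5 and 6, complex V genes 2 and 2, and the complex III gene CYTB 0 and 2. Per kb these were 2.84 and 3.00 in complex I, 1.66 and 1.99 in complex IV, 2.38 and 2.38 in complex V, and 0 and 1.75 in CYTB. ND5 had 5 and 4 widespread alleles, COX1 2 and 3, mt-Rnr1 4 and 2 and mt-Rnr2 1 and 3. Ribosomal RNA genes (odds ratio 0.584, p = 0.128), transfer RNA genes (odds ratio 1.27, p = 0.476) and the third codon positions (odds ratio 1.07, p = 0.882) did not pass Fisher's exact test over both replicates.

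Of the 18 widespread control region alleles in each replicate, 17 were the same. They are among 24 alleles widespread in both replicates and lie between positions 16099 and 16150. Of the 24, 21 had means within 1.2-fold between replicates, such as A16099C at 4.71% and 4.49%. The 17 control region alleles are all transversions, and 3 of the 24 (12.5%) are transitions. Filters on alignment and on nuclear copies of mitochondrial DNA are not given for these counts, so errors of alignment or base calling at these positions were not ruled out. Among alleles under 0.5% in the other replicate the odds ratio was 0 for the control region (Fisher's exact p = 0.640) and 1.5 for protein-coding genes (p = 0.509). At a threshold of 5% it was 0 (p = 0.222) and 9.6 (p = 0.0183, Fisher's exact test).

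The mean fraction of a base change differed between subsets for 4 of 12 changes, a comparison chosen after the values were seen. C>T was highest in Thy, at 13.6 and 14.1 per 10000, and in Thy_6C3, at 13.5 and 13.9, and lowest in CD105, at 11.5 and 11.3 (exact permutation p = 0.00222, one-sided, 0.0267 after adjustment over 12 changes). T>C had the highest mean in 6C3, at 32.1 and 26.1 per 10000, followed by CD29 at 21.2 and 26.5 (adjusted exact permutation p = 0.0476). A>G was at 21.6 and 17.8 in 6C3, which also had the highest mean, and at 15 and 17.9 in CD29 (adjusted exact permutation p = 0.0413). A>T passed as well (adjusted exact permutation p = 0.0413), with 20.8 and 36.7 in Thy, but in replicate 1 CD24_CD29 was higher, at 21.2. With the replicate number as a block, 1 of the 12 changes, C>T, passed after adjustment, and without the Thy subset 8 passed.

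**Figure D5:**
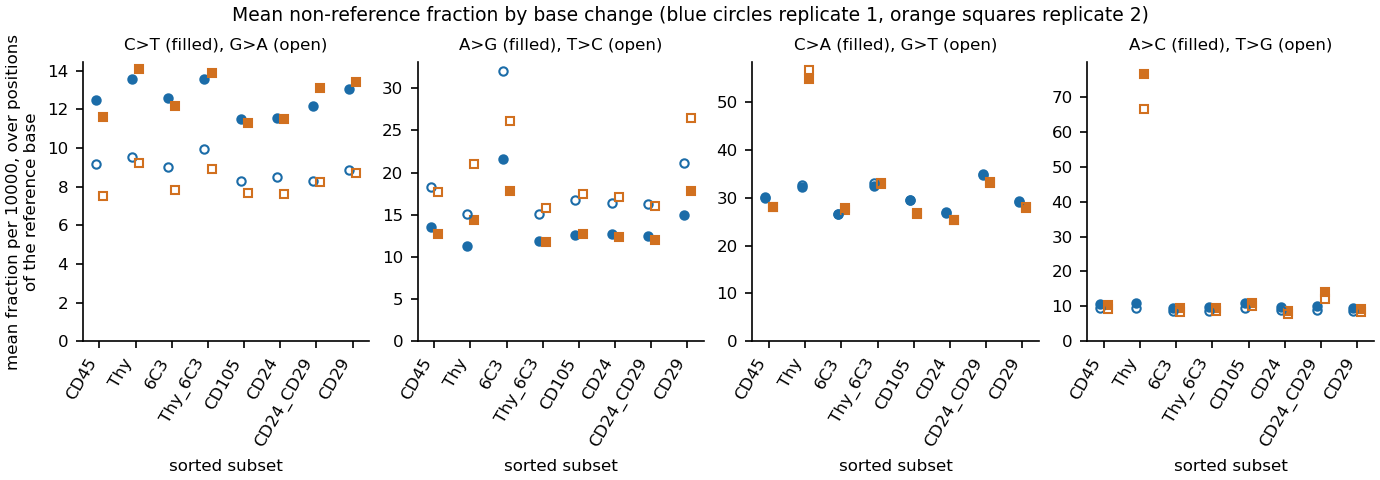
Mean allele fraction per 10000, over positions of the reference base, of 8 base changes in each library, with circles for replicate 1 and squares for replicate 2, filled for the first change named above each panel and open for the second. T>C and A>G are highest in 6C3 replicate 1 at 32.1 and 21.6, and A>C and T>G stand apart in Thy replicate 2.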

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

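All tests that weigh an explanation in this part were chosen after the result was seen. A library was marked where its gap to the nearest of the 8 libraries of its replicate number was large for the range of the group, which chance gives in about 1 of 20 groups. This held in 5 of 8 groups of library measures. The groups are not independent, since load, allele number and transition share in replicate 2 were all marked for Thy replicate 2. The 5 of 8 therefore cannot be set against the chance rate. It also held for 16 of 29 named alleles, each in its replicate number, but these were chosen for their range, their mean or for being counted in a single library, so the chance rate does not apply to them.

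Thy replicate 2 had a mutation load of 1.114%, 2530 alleles at 1% or more and a transition share of 3.79%, against 0.385% to 0.476%, 119 to 416 alleles and 57.6% to 69.8% in the other 7 libraries of replicate 2. After thinning to equal coverage it held 6.27 times the alleles of the next library, which argues against depth, and Thy replicate 1 had 1.76% of its A>C excess, which argues against a property of Thy cells. At 98.8% of A and T positions its A>C or T>G fraction was above that of the 15 other libraries. This is consistent with an error of base calling or library preparation in that library. Which step it arose in was not tested.

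In CD24_CD29 replicate 1, 280 alleles reached 1%, against 98 to 147 in the other 7 libraries of replicate 1, and both CD24_CD29 libraries had many alleles of their own. After thinning to equal coverage, private alleles were still at least 1.92 times those of the next library (Thy replicate 2 set aside), which argues against sequencing depth. The mean C>T fraction was at most 0.470 SD above the other 7, which argues against a higher mutation rate. The median C>T fraction divided by the mean was at most 0.153, the lowest of 8 libraries in both replicates. Few cells or mitochondrial DNA molecules behind these libraries could give such a ratio. It largely restates the pattern, however, since high alleles of their own lower the median relative to the mean, so it cannot decide. Cell numbers were not used here, and a clonal origin of CD24_CD29 cells stays open.

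T>C and A>G fractions had their highest means in 6C3 and CD29. C>A plus G>T in them lay at most -0.370 SD from the mean of the others, which argues against a rise of all errors. The excess of T>C over the excess of A>G in the matching base context of the opposite strand had a lower 95% bootstrap bound of at least 1.32 in the 4 libraries, which argues against an error that strikes both strands alike. The subset test on the summed fractions (exact permutation p = 0.0134, one-sided) only restates the pattern, since these changes were picked because each had passed the same test, and without 6C3 replicate 1 the exact permutation p was 0.0725. A difference between sorted subsets stays open, and so does damage to a single strand during preparation, so the pattern may be technical.

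Other libraries that stood apart are given as values. Mean coverage was 77252 in CD29 replicate 1, with 39931 in the next library of replicate 1. CD24_CD29 replicate 1 had C14338T at 9.09% and T14914C at 7.04%, and no other library of its number was above 0.459%. CD105 replicate 2 had T2539G at 7.64%, T2540G at 6.07% and T2542G at 6.94%, with the next library, Thy replicate 2, at 1.60%, 0.566% and 0.877%. C635T was at 4.29% in CD24_CD29 replicate 2 and 0.748% in the next library of replicate 2, though it averaged 2.76% in replicate 1. A5278C was at 4.04% in Thy replicate 1, with 0.0733% in the next library of its number, and A5202C at 3.46% in Thy replicate 2, with 0.940% in the next. A10457C was at 2.32% in CD24 replicate 1 and 0.0596% in the next. C7913T was at 2.09% in Thy_6C3 replicate 2 and 0.170% in the next, and C14248A at 1.61% in Thy_6C3 replicate 1 and 0.563% in the next. T3200C was at 2.07% in CD29 replicate 2 and 0.958% in the next, and T14833C was at 1.92% in CD29 replicate 1. A14188T was at 1.46% in 6C3 replicate 2 (0.786% in the next), T15014C at 1.44% in CD45 replicate 2 (0.802%) and T9246G at 1.14% in CD45 replicate 1 (0.967%).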

How the results depend on the processing

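Tests of depth, load, allele number, transition share and sharing with a single library left out, settings without Thy replicate 2 with alleles chosen anew, the 2% threshold, alleles of several libraries or of a single replicate number, and leaving out Thy and CD24_CD29 together were chosen after the data were seen. Over 24 results that answer a comparison, 414 of 461 alternatives kept direction and side of the threshold, 4 lost the call, 16 gained it, 21 counts moved by over 1.5 times and 6 reversed. Over 37 results on single alleles, 194 of 206 alternatives were counted as kept and 12 gained a call. For alleles named by mean or range, thinning counted as kept if the mean moved by less than the SD over 8 libraries. That SD was above the mean for C14338T, T14914C, T2539G, T2540G and T2542G, so for them a fall could not fail the check. After thinning, T9246G in CD45 replicate 1 and A16065C in CD105 replicate 1 were at 0.994% and 0.982%, under 1%, and still counted as kept. Coverage minimums of 20 and 500 lay under the lowest coverage and moved nothing, so they test nothing and are not counted. Replicate sharing kept its call in 28 alternatives (0.176 to 1.33), and CD45 and the marker pairs gained none in 19 each. Where no cause is named, the cause was not tested.

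With each subset left out, the exact permutation p ran from 0.00433 to 0.0572 for depth, 0.00598 to 0.317 for load and 0.0325 to 0.314 for allele number, and r of distances from 0.316 to 0.902. With each single library left out and the other of its subset kept, the exact permutation p ran from 0.00815 to 0.0611 for depth, 0.000399 to 0.338 for load, 0.00217 to 0.343 for allele number and 0.0159 to 0.271 for the transition share. The low ends for load, allele number and transition share, and the 0.902, came without Thy libraries. Where a single library was left out, the low ends of these measures came without Thy replicate 1. Thy replicate 2 is then alone in its subset and adds nothing to the spread within subsets, so they show no difference between subsets. The transition share passed at a threshold of 0.5% (p = 0.00140) and weighted by fraction (p = 0.0296), both by the exact permutation test. The r of distances passed at a 2% threshold (0.746), with alleles in at least 2 libraries (0.755) and with alleles widespread in a single number (0.633), and was -0.0280 at 5%.

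Counts of alleles called by edgeR with a library left out ran from 0 to 2298 over all subsets, 0 to 2396 for Thy, 0 to 147 for CD24, 0 to 25 for CD24_CD29 and 0 to 1 for 6C3. The lone library left in a subset is then assumed to vary like the others. The highest counts came without Thy replicate 1, which leaves Thy replicate 2, and for CD24_CD29 without its replicate 1. DESeq2 called 18 over all subsets, 2024 for Thy, 6 for Thy_6C3 and 67 for CD24_CD29. The quasi-binomial model called 2259 for Thy and 30 for CD24_CD29, and edgeR without a fraction filter 2 for Thy. The replicate block called 2 for Thy and 1 for Thy_6C3, and changed no other count of edgeR calls. The block without Thy replicate 2 called 1 for Thy and 1 for Thy_6C3.

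At a threshold of 5%, 19 and 16 alleles differed between libraries of replicates 1 and 2, with fewer alleles tested, and 738 of replicate 2 did without Thy replicate 2. The odds ratio of widespread alleles reversed for protein-coding genes to 9.6 at 5%, 1.5 among alleles under 0.5% in the other replicate and 1.87 when Thy replicate 2 was also left out, and for the control region to 0 in all 3. Ribosomal RNA genes passed at 0.5% (0.589) and without Thy replicate 2 (0.428), and transfer RNA genes at 0.5% (1.5). Depth limits low fractions most in CD24_CD29 replicate 2, where 3 counts are 0.0457% at the mean coverage.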

Other observations

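All tests in this part were chosen after the values were seen. Some A>C changes in transfer RNA genes were high in Thy libraries, and were named here after their values were seen, with no test of enrichment in these genes. A5202C in TrnC was at 3.07% in Thy replicate 1 and 3.46% in Thy replicate 2, with 0.0590% to 0.940% in the other libraries of either replicate. A5278C in TrnY was at 4.04% in Thy replicate 1, 0.778% in Thy replicate 2 and at most 0.228% in the other libraries, and the adjacent A5277C was at 2.60% in Thy replicate 1. The value of A5278C in Thy replicate 2 is close to the mean of all A>C changes in that library, 76.5 per 10000.

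Several high alleles were shared by both replicates at unequal levels. C7953T in ATP8 and ATP6 averaged 10.7% in replicate 1 and 1.86% in replicate 2, C14024T in ND6 5.26% and 9.10%, and C7166T in COX2 9.34% and 6.49%. They are 3 of the 24 alleles widespread in both replicates, where 0.0640 would be expected if the lists were independent. The other 21, of which 17 lie in the control region, had nearly equal means in both.

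If 2 changes lay on the same mitochondrial DNA molecules, their fractions would rise and fall together over the libraries of a replicate. Among 27 alleles of replicate 1 and 32 of replicate 2, 847 pairs were tested by correlation over 8 libraries with an exact permutation test (40320 orders, two-sided, smallest p 2.48e-05). For both changes on the same mitochondrial DNA molecules, 0 pairs had a positive correlation with an adjusted p under 0.05, while 88 passed unadjusted where 42.4 are expected. In simulated data with 8 libraries, 100% of 3 closely linked pairs among 435 (lowest r 0.998) were recovered, with 0 false calls. Looser links were not simulated, so the question stays open. Of all pairs, 49.8% had a negative correlation, which argues against a factor of the library that scales every allele alike.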
